A study of Homo sapiens with 2 samples.

How the data were processed

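Messenger RNA of the human pancreatic ductal cancer cell line PANC-1 was profiled on single-colour NimbleGen expression arrays with Cy3 label, per the labels' protocols. The cells had been pretreated, in the labels' wording, for 24 h with clofibrate or with its solvent control DMSO. There was 1 array per group, 2 arrays in all. The clofibrate dose, and whether the samples came from independent cultures, are not given in the sources used here. NimbleGen arrays carry synthetic oligonucleotide probes. Each transcript has 3 probes (fewer for 2 transcripts), summarised to 1 value per the file headers.

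Each deposited array file holds an RMA intensity on a linear scale for 45033 human transcripts, placed on genome build HG18 per the file headers and rows. RMA (robust multi-array averaging, which combines background correction, normalization between arrays and summary over probes) is named in the submitters' processing notes. Its software and version are not given in the sources used here. The quantiles of the arrays nearly coincide, with medians of 401.7 for DMSO and 401.7 for clofibrate, so a shift of all transcripts in 1 direction could not be seen in these values. The deposited files also hold the count of probes that were summarised into each row, a raw count per the file headers. A further deposited score per row was computed by the authors and is named as a standard error per the file headers, its scale is not given in the sources used here, and it was not used. A control row that the files call random, with 5000 probes, gave 48.7 in the DMSO array and 48.1 in the clofibrate array and served as a background level. The series value table was identical to the array files in every row (largest difference 0), so the alternative that uses it could not move any result.

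From these intensities log2 values were computed with no pseudocount, and the difference is always clofibrate minus DMSO. Of the transcripts, 42947 carry an Entrez gene ID and 2086 do not. The former make up 23619 genes, and a gene's value is the mean log2 over its transcripts. Of these genes, 11759 have 1 transcript and 11860 have more. Values of single transcripts are given for only some of the latter, and the transcripts of others can disagree too, also in sign. Gene symbols were updated through the Entrez ID with a RefSeq gene table of GRCh38.p14, which holds 20230 of the IDs. The other 3389 genes keep the symbol of the files. No coordinates of that table were used. Genes were called expressed when their mean log2 value over both arrays was at or above the median of all genes, an intensity of 363.7. This left 11810 genes. No file gives a detection call, and the number of arrays limits the precision.

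With 1 array per group there is no estimate of the spread between cultures. No test across samples was made and no p-value is given. Differences are described by size, with a threshold of 2-fold. The spread between transcripts of 1 gene is given as a partial measure of error. It covers probe and hybridisation noise within these arrays and not the difference between cultures. Transcripts of 1 gene may share probes, which could not be checked without probe sequences. The spread may therefore be too small, and concordant transcripts need not be independent measurements. For 34 gene lists, the median difference over expressed members was set against the medians of 10000 random lists of the same size, drawn from expressed genes in the same of 20 bins of mean expression. Lists with at least 5 expressed members were placed this way. A percentile under 2.5 or over 97.5 is described as standing apart. This describes these 2 arrays and is not a test of the treatment, and genes of a list are not independent replicates. The lists, the thresholds and the rule for naming genes were fixed before the data were examined. The rule names the 12 highest and 12 lowest differences among expressed genes whose transcripts all share a sign, leaving out placeholder symbols, then the 2 highest and 2 lowest expressed members of each list, and always PPARA, PPARD, PPARG, RXRA, PTPRZ1, WNT8A, CTNNB1, APC, MYC and CCND1. PTPRZ1 and WNT8A stand in the rule from an unchecked recollection that the study followed them up, so they count as chosen on these arrays. Some genes that the rule takes are not reported here. List symbols UGT1A6, UGT1A9, HSPA1B and ATP5A1 had no match and were left out.

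Alternatives were the series value table, centring on the median difference, a loess fit of the difference on mean log2 value (span 0.4), the brightest transcript per gene, other filters (none, the 25th and the 75th percentile), thresholds of 1.5-fold, 3-fold or 3 local robust SDs (50 bins of brightness), transcripts in place of genes, and the mean in place of the median of a list. A filter on the brighter array was added after seeing the data. To weigh gene surroundings, the differences of expressed genes were regressed on the ranks of mean log2 value, genomic span and genes per 1 Mb (cubic terms). The fits on mean log2 value alone and on span and density alone were added after the joint fit was seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with figures by matplotlib 3.10.9. The calculations were tested on simulated data with the real means and local spread of the 11810 expressed genes. There, 98% of 100 genes changed by 1.5 on the log2 scale and 75% of 100 genes changed by 1.2 passed 2-fold, as did 2 of 11580 unchanged genes. The simulated noise was normal and independent between genes, with the robust local SD. It held no outlying transcripts and no spread between cultures. The 2 unchanged genes are therefore not an estimate of how many real genes passed 2-fold through noise. A planted list of 30 genes shifted by 0.2 reached percentile 99.99, and 4.5% of 200 random lists stood apart.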

Results

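PANC-1 cells, an epithelial line derived from a human carcinoma of the pancreatic duct, were pretreated for 24 h with clofibrate or with DMSO. Clofibrate is a fibrate, a lipid-lowering drug whose active form is an agonist of the nuclear receptor PPARα. Total RNA of 1 sample per group was hybridised to 1 array each. The middle 50% of intensities lay between 116.8 and 1136 in the DMSO array and between 117.1 and 1138 in the clofibrate array. The share of transcripts at or over 2 times the random-probe background was 78.0% and 78.3%. Without replicates, no difference below has a check against the spread between cultures. The comparison asks which mRNAs differed between clofibrate and DMSO.

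The arrays were close to each other. Across 45033 transcripts the log2 values correlated with Pearson's r = 0.982 (across transcripts, which are not independent replicates). Of 11810 expressed genes, 97.3% lay within 1.5-fold. The SD of the differences was 0.26 on the log2 scale, and their median was 0.013. At least 2-fold higher with clofibrate were 16 expressed genes, and at least 2-fold lower were 13, together 0.246% of those measured. All but 1 of the 29, CSF3, lay among the 5905 dimmer expressed genes. Below the filter, where the SD was 0.45, another 227 genes were at least 2-fold higher and 202 at least 2-fold lower. In 5792 genes with several transcripts over the filter, the gap between the differences of 2 transcripts of a gene had an SD of 0.34, or 0.24 for a single transcript. Across these genes the differences of the 2 transcripts correlated only weakly (Pearson's r = 0.27, Spearman's rho = 0.31). The differences of the first of the 2 transcripts had an SD of 0.28, little more than 0.24. Differences of that size in a single transcript are therefore not told apart from disagreement between transcripts.

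CSF3, the granulocyte colony-stimulating factor, had the largest positive difference among expressed genes. Its intensity was 1323 with DMSO and 4358 with clofibrate, 3.29-fold higher, and no other of the 472 genes of like brightness differed as far upward. Its transcript spans chromosome 17, 35425213 to 35427592 (HG18). FUT7, a fucosyltransferase that builds sialyl Lewis X, followed with 254.2 and 752.9 (2.96-fold). ARHGEF25, an exchange factor for the small GTPase RhoA, was 2.88-fold higher, and both of its transcripts on chromosome 12 showed it, with log2 differences of 1.41 and 1.64. The spans of these 2 transcripts overlap almost fully, so they may share probes. Further named genes with higher values were LINC01599, a non-coding RNA (2.72-fold), EEIG1 (2.16-fold), the keratin pseudogene KRT126P (2.15-fold), the sodium/proton exchanger SLC9A4 (2.13-fold), YJU2B (2.06-fold), the kinase PSKH2 (2.05-fold), the NADPH oxidase subunit NCF4 (2.02-fold) and TCEB3C (2.02-fold). ARHGEF25 was the only one of these with more than 1 transcript. Other genes past 2-fold included MYO7A and genes with placeholder symbols.

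Most of the 13 genes at least 2-fold lower have placeholder symbols and are not named, with the lowest at a log2 difference of -2.29. Among named genes with lower values, 4 passed 2-fold. These were CCDC184 (2.18-fold lower), SH2D7 (2.18-fold lower), PRKG2, a cGMP-dependent protein kinase (705.0 with DMSO and 327.2 with clofibrate, 2.15-fold lower), and CIROZ (2.02-fold lower). The next 8 were between 1.82 and 1.93-fold lower. They were the ubiquitin-conjugating enzyme UBE2E1, SPANXA2, the meiotic histone methyltransferase PRDM9, the guanine nucleotide exchange factor ARHGEF6, the lysine-degrading enzyme AASS, PRB2, LCN1P2 and NACA2. All 12 rest on a single transcript each. SPANXA2, PRB2, LCN1P2, NACA2, KRT126P and TCEB3C belong to families with close copies whose RNA the probes may share, so their identity is uncertain.

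**Figure D1:**
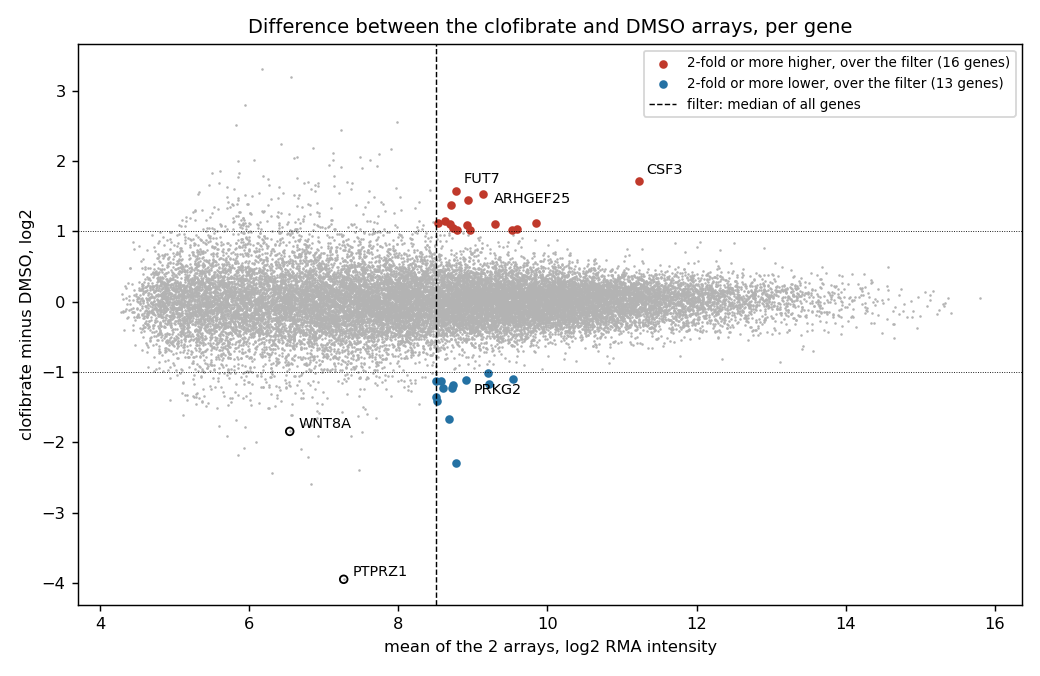
Difference between the clofibrate and DMSO arrays (log2, y axis) against the mean log2 RMA intensity of both arrays (x axis), 1 point per gene. Red and blue points are the 16 and 13 genes at least 2-fold higher or lower over the expression filter (dashed line), dotted lines mark 2-fold, and open circles mark PTPRZ1 and WNT8A, which lie below the filter (WNT8A at the mean of its 2 transcripts, 1 of them under the background).

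PTPRZ1, a receptor-type protein tyrosine phosphatase, and the Wnt ligand gene WNT8A had the transcripts with the largest measured reductions on the array. The only PTPRZ1 transcript (chromosome 7, 121300642 to 121489326, HG18) read 604.2 with DMSO and 39.2 with clofibrate, under the random-probe background of 48.1. Taken against that background it was at least 12.6-fold lower. Its mean over both arrays lay below the expression filter, so it is not among the 13 genes above. One WNT8A transcript (chromosome 5, 137447577 to 137455953) read 857.7 and 64.8, 13.2-fold lower, while the other, with the same span, read 36.3 and 37.3, under the background in both arrays. The order of the PTPRZ1 and WNT8A reductions is not settled, since the PTPRZ1 value is a bound. The WNT8A reading of 64.8 with clofibrate is also less than 2-fold over the background, so its fold is uncertain too. The gene mean of WNT8A, which averages in the undetected transcript, lay below the filter. Both genes were named from an unchecked recollection that the study followed them up from these arrays, so they are not independent evidence. At least 4-fold differences were seen in 33 transcripts downward and 39 upward. In the 6 genes among these with another transcript over the filter, the other transcripts differed in the same direction by a median of only 0.13. Since the first transcripts were picked for their size, a smaller difference in the others follows in part from that choice.

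At the gene level, the PPAR genes and RXRA lay within 1.5-fold. PPARA, the receptor for fibrates, read 489.4 and 515.8, a log2 difference of 0.076, but its 4 transcripts ran from -0.33 to 0.75. PPARD was 1.45-fold higher (1 transcript), and 13 of 472 genes of like brightness were as far up. PPARG lay below the filter with a difference of -0.10, and its 4 transcripts ran from -0.89 to 0.20. RXRA, the partner of PPAR receptors, differed by 0.36, with its 5 transcripts between -0.50 and 1.23. CTNNB1, which encodes β-catenin, read 5405 and 5318 (-0.023). APC, a part of the β-catenin destruction complex, differed by -0.10 and lay below the filter. The β-catenin targets MYC and CCND1 differed by -0.16 and -0.073.

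Genes known as PPARα targets were not shifted as a group. Of 26 expressed members, 15 were higher and 11 lower, none by 2-fold, and the median of 0.048 lay at percentile 73.0 of random lists (-0.048 with the brightest transcript). The highest were ACOT1, an acyl-CoA thioesterase (0.54, with the close copy ACOT2 at 0.087), and ACADVL, very-long-chain acyl-CoA dehydrogenase (0.37). The lowest were the acyl-CoA synthetase ACSL3 (-0.55, its 2 transcripts at -0.97 and -0.12) and malic enzyme ME1 (-0.28, its 2 transcripts at -0.61 and 0.050). A further 21 members lay below the filter. One of them, ANGPTL4, a secreted inhibitor of lipoprotein lipase, read 166.6 and 409.9, 2.46-fold higher. It was the only member past 2-fold and was singled out after its values were seen. Of 472 genes of like brightness, 2 including ANGPTL4 were as far up. PDK4 (-0.049) and CPT1A (0.40), also chosen after the values were seen, lay below the filter.

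Genes for peroxisome function had the highest median of all lists, 0.16 or 1.12-fold, at percentile 99.3. Of 21 expressed members, 13 were higher and 8 lower, and 9 more lay below the filter. The import factor PEX26 was higher by 0.45, in both of its transcripts. PEX3 (-0.50) and the transporter ABCD3 (-0.34) were lowest. This list reversed to a median of -0.090 when the brightest transcript stood for each gene, and it did not stand apart without the filter, with either other filter or with the mean. Mitochondrial fatty acid oxidation had a median of 0.084 over 18 of 21 measured genes, 10 higher and 8 lower (percentile 84.9), from ACAD9 (0.45) and ACADVL (0.37) to ACADM (-0.23) and ECI2 (-0.26). Cholesterol synthesis had a median of 0.066 over 23 of 24 genes, 14 higher and 9 lower (percentile 81.0), with MVK at 0.33 and TM7SF2 at 0.29, and with HMGCS1 at -0.30 and CYP51A1 at -0.25. Fatty acid synthesis lay at 0.010 over 18 of 23 genes, 9 higher and 9 lower (percentile 47.2), with a mean of -0.052, between ELOVL1 (0.51) and FADS2 (0.34) above and ACSL4 (-0.51) and ACSL3 below. With the brightest transcript it was -0.079.

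**Figure D2:**
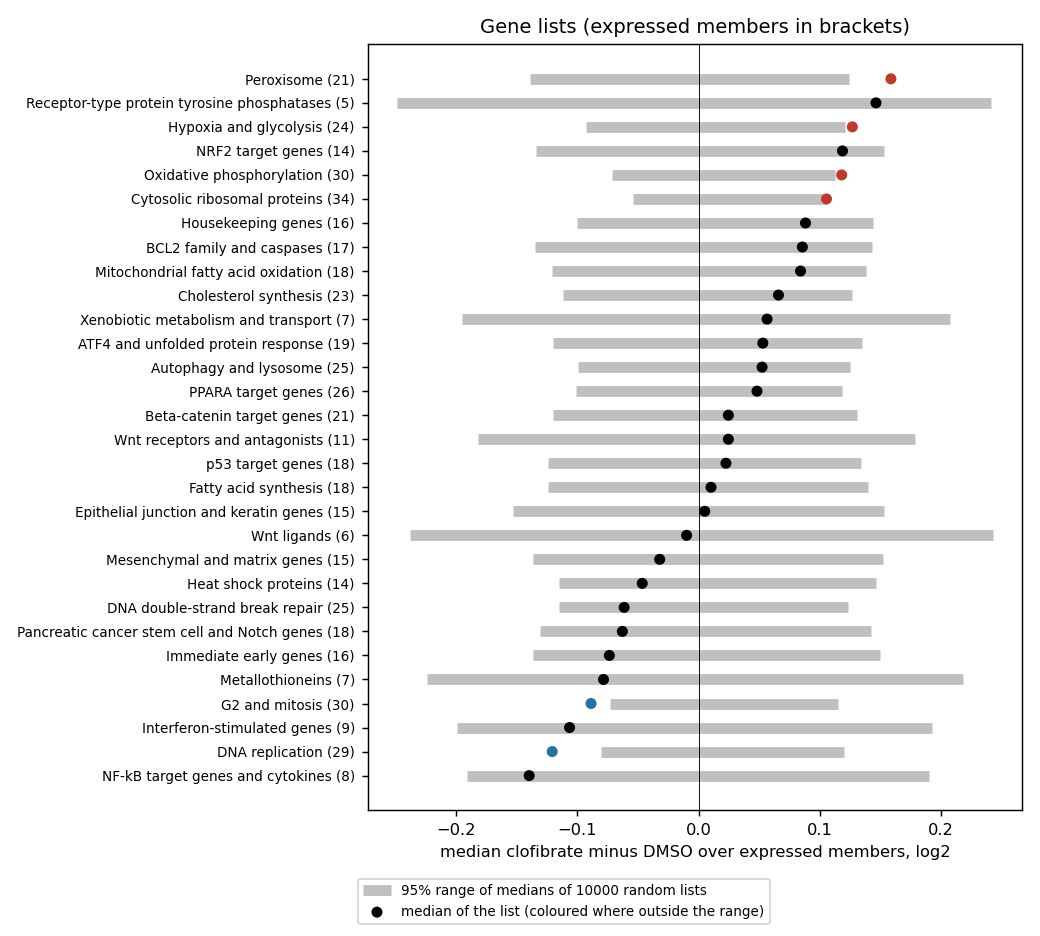
Median difference between clofibrate and DMSO (log2, x axis) of each gene list with at least 5 expressed members. Dots are list medians and grey bars the 95% range of medians of 10000 random lists matched on size and expression. DNA replication (-0.12) and G2 and mitosis (-0.089) lie to the left of their bars, and peroxisome (0.16), hypoxia and glycolysis, oxidative phosphorylation and cytosolic ribosomal proteins to the right.

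Genes of DNA replication were lower by a small amount. Of 29 expressed members (1 below the filter), 20 were lower and 9 higher, and the median of -0.12, or 1.09-fold, lay at percentile 0.35. The replicative helicase subunit MCM6 (-0.36) and the polymerase subunit POLA1 (-0.36) were lowest, and MCM5 (0.24) and GINS3 (0.17) highest. Genes of G2 and mitosis were lower in 19 of 30 cases, with a median of -0.089 (percentile 1.12). The spindle protein NUSAP1 (-0.59) and the kinetochore protein CENPF (-0.40) were lowest, while the centromeric histone CENPA (0.34) and the kinase PLK1 (0.29) were highest. No member of either list reached 2-fold. Both lists stood apart under every alternative run, though the series value table and centring could not change a percentile. In these arrays, however, differences also ran with gene surroundings. The 2362 genes with the densest surroundings (median of 38 genes per 1 Mb) had a median of 0.094, and those with the sparsest (median of 5) -0.072. After a regression on mean log2 value, genomic span and gene density, DNA replication lay at percentile 3.48 and G2 and mitosis at 0.62. With span and density alone the percentiles were 3.53 and 0.58, and with mean log2 value alone 0.745 and 0.90. Double-strand break repair, with 9 of 25 expressed genes higher, 16 lower and 5 below the filter, had a median of -0.061 (percentile 12.2). XRCC5, the Ku80 subunit, differed by -0.43 in 3 concordant transcripts and the helicase BLM by -0.42. XRCC3 was at 0.34, and DCLRE1C at 0.37 with its 3 transcripts spread from -0.52 to 1.94.

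The lists of hypoxia and glycolysis, oxidative phosphorylation and cytosolic ribosomal proteins had slightly higher medians. Hypoxia and glycolysis genes had 19 of 24 expressed members higher (4 below the filter) and a median of 0.13 (percentile 98.2), from hexokinase HK1 (0.51) and the growth factor VEGFA (0.47, transcripts from -0.047 to 1.14) to KDM3A (-0.13) and BNIP3L (-0.55). Oxidative phosphorylation had 21 of 30 expressed members higher (3 below the filter) and a median of 0.12 (percentile 98.3). NDUFB8 (0.37) and NDUFA4, now COXFA4 (0.36), were highest and UQCRC2 (-0.20) and SDHC (-0.15) lowest. Cytosolic ribosomal proteins had 24 of 34 members higher and a median of 0.11 (percentile 97.6), from RPL37 (0.43) to RPL6 (-0.14) and RPL4 (-0.31). Ribosomal proteins did not stand apart under 4 of the 8 alternatives (loess, the brightest transcript, no filter and the 75th percentile), nor hypoxia and glycolysis with the brightest transcript. After the same regression the percentiles were 96.3, 92.8 and 72.1, and that of peroxisome genes was 97.2. In all, 6 of the 30 lists stood apart, where 1.5 are expected by chance for independent lists. The regression was run only on these 6 lists, and of them only G2 and mitosis still stood apart after it. The other lists were not placed after the regression, so no count after it can be set against chance.

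**Figure D3:**
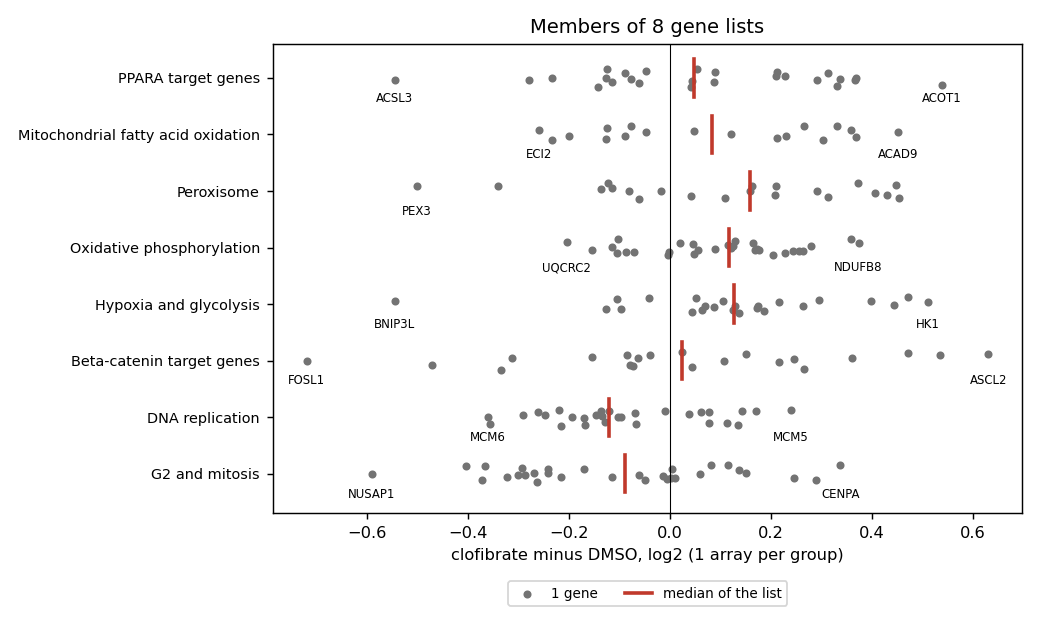
Difference between clofibrate and DMSO (log2, x axis) of each expressed gene in 8 lists. Grey points are genes, red bars list medians, and members at the ends of lists are named in most cases; all lie within 2-fold, from FOSL1 (-0.72) to ASCL2 (0.63).

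Wnt signalling genes were not shifted as groups. Only 6 of 19 Wnt ligand genes were over the filter, 2 higher and 4 lower, with a median of -0.0098 (percentile 46.3), from WNT9A (0.17) and WNT3A (0.034) to WNT2B (-0.13) and WNT4 (-0.30). Wnt receptors and antagonists had a median of 0.025 over 11 of 28 genes, 6 higher and 5 lower (percentile 58.8), with a mean of -0.0039. LRP5 (0.40) and SFRP5 (0.31) were highest, FZD2 (-0.34) and ROR1 (-0.31) lowest. The 21 expressed β-catenin target genes had a median of 0.025 (percentile 58.0), with 11 higher and 10 lower and 10 below the filter, and were at -0.047 with the brightest transcript, -0.063 with no filter and -0.056 at the 75th percentile. ASCL2 (0.63) and PPARD were highest, and the AP-1 subunit FOSL1 (-0.72) and the transcription factor LEF1 (-0.47, its 2 transcripts at -0.85 and -0.093) lowest. Of 20 receptor-type phosphatase genes, 5 were expressed, 4 higher and 1 lower, with a median of 0.15 (percentile 87.5). They included PTPRN (0.33), PTPRU (0.29), PTPRF (0.10) and PTPRA (-0.26). With no filter all 20 counted, 8 higher and 12 lower, and the median was -0.11. Stem cell and Notch genes had a median of -0.063 over 18 of 30 genes, 6 higher and 12 lower (percentile 14.5), from NOTCH1 (0.45) and JAG2 (0.37) to SOX2 (-0.31) and DLL1 (-0.35), and stood apart with the brightest transcript (-0.15). Mesenchymal and matrix genes had a median of -0.032 over 15 of 30 genes, 5 higher and 10 lower (percentile 26), between COL6A1 (0.19) and TWIST1 (0.14) and CCN1 (-0.33) and SNAI1 (-0.47). Epithelial junction and keratin genes lay at 0.0051 over 15 of 28 genes, 8 higher and 7 lower (percentile 49.6), between ST14 (0.40) and PKP3 (0.21) and OCLN (-0.23) and CRB3 (-0.25), and at -0.091 with the brightest transcript and -0.11 at the 75th percentile.

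The medians of stress and death genes lay within the range of random lists. Under alternatives, heat shock proteins stood apart with the mean (-0.11), and autophagy and lysosome genes with no filter and at the 25th percentile (0.13 each). The median turned to -0.016 for BCL2 family and caspase genes with the brightest transcript, and for ATF4 and unfolded protein response genes to -0.041 with no filter and -0.023 at the 25th percentile. The 18 expressed p53 target genes of 24, 10 higher and 8 lower, had a median of 0.023 and a mean of -0.0080 (percentile 55.6), with the repair factors DDB2 (0.41) and XPC (0.35) highest and ZMAT3 (-0.49) and TIGAR (-0.50) lowest. BCL2 family and caspase genes had a median of 0.086 over 17 of 29 genes, 12 higher and 5 lower (percentile 86.2), with APAF1 at 0.31, CASP9 at 0.24 and PMAIP1 at -0.33. ATF4 and unfolded protein response genes had a median of 0.053 over 19 of 27 genes, 11 higher and 8 lower (percentile 70.5). DDIT4, an mTORC1 inhibitor, was higher by 0.61, in both of its transcripts, and CALR by 0.37, while HSP90B1 (-0.41) and EDEM1 (-0.23) were lowest. NRF2 target genes had a median of 0.12, with 12 of 14 expressed genes higher and 10 below the filter (percentile 92.5), from TKT (0.31) and GSR (0.28) to HMOX1 (-0.056) and ME1. Heat shock proteins had a median of -0.046 over 14 of 17 measured genes, 5 higher and 9 lower (percentile 14.7). HSPH1 (-0.56) and HSPD1 (-0.47) were lowest, and HSPA1A (0.26, a near-identical copy of HSPA1B) and DNAJB1 (0.086) highest. The 7 expressed metallothioneins of 11, 2 higher and 5 lower, had a median of -0.078 (percentile 24.6), from MT1X (0.14) and MT1A (0.071) to MT1G (-0.16) and MT1E (-0.30). The 25 expressed autophagy and lysosome genes of 27, 15 higher and 10 lower, lay at 0.052 (percentile 71.5), from GLA (0.38) and CTSD (0.34) to NPC1 (-0.37) and NPC2 (-0.39).

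Inflammatory genes gave a divided picture. Apart from CSF3, the expressed NF-κB target genes and cytokines were flat or lower, with IRAK2 at 0.076, TRAF1 at -0.16 and NFKBIA at -0.30. Their median over 8 of 30 genes, 2 higher and 6 lower, was -0.14 (percentile 7.54), while their mean, set by CSF3, was 0.10. Immediate early genes had a median of -0.074 over 16 of 28 genes, 7 higher and 9 lower (percentile 13.8), from IER5 (0.24) and ZFP36 (0.11) to FOSB (-0.33) and FOSL1. Of 30 interferon-stimulated genes 9 were expressed, 4 higher and 5 lower, with a median of -0.11 (percentile 14.8), between IRF9 (0.70) and USP18 (0.45) and SAMD9 (-0.46) and IFIT5 (-0.67). This list stood apart with the filter at the 25th percentile (-0.19), but the brightest transcript turned it to 0.19, so its direction is not settled. Xenobiotic metabolism and transport genes, 7 of 30 expressed, 5 higher and 2 lower, had a median of 0.057 (percentile 63.7). CYP1B1 (0.53) and GSTP1 (0.47) were highest and GSTA4 (-0.15) and ABCB1 (-0.34) lowest.

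Markers of other cell types were mostly below the filter. Of hepatocyte markers 1 of 19 was over it (AMBP, 0.19). The fibroblast and endothelial list had 1 of 18 (COL1A1, -0.090). The blood and immune list had 4 of 22 (among them HBA2 at 0.54, CD4 at 0.52 and HBA1 at -0.29). The acinar, ductal and islet list had 3 of 20 (PDX1 at 0.34, CEL at -0.089 and PTF1A at -0.26). These lists had too few members for a percentile. Housekeeping genes had 13 of 16 members higher and a median of 0.088 (percentile 83.4), with PGK1 at 0.40, TFRC at -0.28 and YWHAZ at -0.31, which sets the size of differences that reference genes showed between these arrays.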

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

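Among the 2086 transcripts without a gene name, which enter no gene count or list, 898 lay over the expression filter, and 2 of these were at least 2-fold higher with clofibrate than in the DMSO control. They drew attention as signal outside the genes reported on. AY358807 (chromosome 6, 4989978 to 4990898, HG18) read 386.8 with DMSO and 1647 with clofibrate, a log2 difference of 2.09. AY358246 (chromosome 6, 30086584 to 30088026) read 305.6 and 841.2, a difference of 1.46. Another 4 unnamed transcripts were at least 2-fold lower, the furthest of them BC098428 on chromosome 1 (116748858 to 116762728), which read 784.3 and 278.0. No explanation was tested for these transcripts.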

How the results depend on the processing

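The filter on the brighter array was chosen after seeing the data; the other alternatives were planned. The series value table moved nothing, being identical. Centring moved no count or list past its limits, but it shifts all genes by the same amount and so could not change a list's percentile. The numbers of genes at least 2-fold higher with clofibrate and of genes at least 2-fold lower with clofibrate were 243 and 215 with no filter, 94 and 81 with the filter at the 25th percentile, 1 and 0 at the 75th percentile, 36 and 34 with the brighter array over the filter, 155 and 158 at 1.5-fold, 1 and 2 at 3-fold, 63 and 45 beyond 3 local robust SDs, and 48 and 35 for transcripts in place of genes. With the brightest transcript 25 genes were higher and 13 lower. DNA replication, G2 and mitosis and oxidative phosphorylation stood apart under all 8 alternatives run on lists, and hypoxia and glycolysis under all but the brightest transcript (0.12, percentile 97.2). The brightest transcript reversed the peroxisome median to -0.090. It also gave PPARA targets -0.048, fatty acid synthesis -0.079, Wnt ligands -0.13, β-catenin targets -0.047, BCL2 family and caspases -0.016, interferon-stimulated genes 0.19, epithelial genes -0.091, ribosomal proteins 0.040, and stem cell and Notch genes -0.15, which then stood apart. Loess adjustment gave ribosomal proteins 0.085, no longer apart. With no filter, peroxisome (0.025) and ribosomal proteins (0.11) no longer stood apart, autophagy and lysosome did (0.13), and β-catenin targets were at -0.063, ATF4 and unfolded protein response at -0.041 and receptor-type phosphatases at -0.11. At the 25th percentile, peroxisome (0.076) no longer stood apart, interferon-stimulated genes (-0.19) and autophagy and lysosome (0.13) did, and ATF4 and unfolded protein response was at -0.023. At the 75th percentile, which left 24 lists, peroxisome (0.10) and ribosomal proteins (0.10) no longer stood apart, and cholesterol synthesis was at 0.13, fatty acid synthesis 0.11, β-catenin targets -0.056, immediate early genes -0.15, mesenchymal genes -0.13 and epithelial genes -0.11. With the mean, peroxisome (0.11) no longer stood apart, heat shock proteins (-0.11) did, and NF-κB targets turned to 0.10, set by CSF3. Of the single-gene values, 606 stayed within their limits and 22 moved, all with the brightest transcript. Many of the 606 had no room to move, so their number does not measure robustness. The series value table is identical, centring shifted every gene by only 0.0036, and the brightest transcript cannot change a gene with 1 transcript. Filters and thresholds change the counts by their construction; for the lists the cause was not tested. Signal near background limits dim genes most. No paired analysis was possible because each group has 1 array, which also rules out leaving an array out.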

Other observations

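The grouping of gene families by the stem of their symbol, and the single-transcript tests of PTPRZ1 and WNT8A, were chosen after the results were seen. The families gave further small shifts. Of 62 families with at least 15 expressed members, 8 stood apart from random lists, where 3.1 are expected by chance. Genes with the stem INTS, most of them subunits of the Integrator complex, which processes small nuclear RNAs, and among them the pseudogene INTS4P1, were lower in 10 of 15 cases, with a median of -0.25 (percentile 0.04), from INTS8 (-0.43) and INTS2 (-0.41) to INTS11 (0.23) and INTS15 (0.29). Kinesin motor genes were lower in 22 of 28 cases (median -0.14, percentile 0.56), with KIF14 (-0.53) lowest and KIF1C (0.48) highest. Genes with the stem CEP, mostly centrosomal and with the pseudogene CEP57L1P1 among them, were lower in 18 of 23 cases (median -0.17, percentile 0.50), with CEP170 at -0.53, CEP152 at -0.46 and CEP135 at -0.45. Genes with the stem EIF, which include translation initiation factors but also kinases, binding proteins and pseudogenes, had a median of -0.060 over 55 members (percentile 1.57).

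HNRNPA genes were lower in 20 of 21 cases (median -0.21), but most of these members are pseudogenes whose probes may share RNA with HNRNPA1 (-0.21). Probe sequences were not given, so this was not tested, and the members cannot be counted as separate measurements. The same caution applies to the stem RPS, higher in 74 of 92 cases (median 0.10, percentile 99.9). It holds pseudogenes, ribosomal protein genes and other genes such as RPS6KB1. Genes with the stem VPS, mostly of vacuolar sorting, were higher in 18 of 27 cases (median 0.15, percentile 99.4), from VPS35L (0.50) to VPS54 (-0.78). Genes with the stem SLC, mostly solute carriers but with pseudogenes and other genes among them, were higher in 119 of 194 cases (median 0.063, percentile 99.5). After the regression on mean log2 value, genomic span and gene density, 5 of the 8 families still stood apart, and the CEP, EIF and VPS genes were at percentiles 6.65, 4.39 and 96.6. Another 7 families stood apart only after it, 12 in all: KRTAP, OR, ZNF, DDX and LRRC genes lower and RPL and COX genes higher. The 43 KRTAP and 29 OR genes, at percentiles 0.04 and 0.17, passed the filter on intensity alone, without a detection call. Whether they were transcribed in these cells is not known from the arrays. A family that stands apart therefore need not be one whose mRNA changed.

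The small shifts of gene lists may partly follow the genomic span and local gene density of their members. These properties differ between lists, with a median span of 4482 bp for cytosolic ribosomal proteins and 25569 bp for G2 and mitosis. A regression on them may therefore also remove differences tied to function. By genomic span, groups of 2362 genes had medians of 0.052 in the shortest (median span 1560 bp), 0.070 in the next and -0.078 in the longest (104503 bp), and by local gene density medians ran from -0.072 to 0.094. A regression on both and on mean log2 value argues against these trends as the whole cause for G2 and mitosis, which stayed at percentile 0.62. It took cytosolic ribosomal proteins to percentile 72.06 (median from 0.11 to 0.031), and span and density alone took them to 70.7 but mean log2 value alone only to 97.46, so the trend is a candidate explanation, although the stems RPS and RPL, with many pseudogenes, were at 99.99 and 98.4 after it. It left undecided DNA replication (3.48, median from -0.12 to -0.078), peroxisome (97.19), hypoxia and glycolysis (96.33) and oxidative phosphorylation (92.81), and GC content, RNA quality, culture density and clofibrate itself stay open, untested.

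The 4-fold and larger differences may come from faults of single probe sets on 1 array. In 6 such transcripts whose gene had another transcript over the filter, the other transcripts differed, in the same direction, by a median of only 0.1305, from -0.18 (SPAG11A, opposite) to 0.58 (TBXA2R). They included AXL, with 2.44 in 1 transcript and 0.062 in the other, and MEG3, with -3.09 in 1 transcript and -0.26 over its 2 others. The first transcripts were picked as the most extreme, with no filter on their own intensity. Over the filter, 2 transcripts of a gene correlated only weakly in their differences (Pearson's r = 0.27). A much smaller difference in the others is then likely from the selection alone, so the check cannot single out probe faults. Changes in single isoforms stay open as well. For PTPRZ1 and WNT8A this check decides nothing, because PTPRZ1 has only 1 transcript on the array and the other WNT8A transcript was at 36.3378 in the DMSO array, under the background.

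PTPRZ1 and the gene next to it on chromosome 7, AASS (121503422 to 121561112, HG18), were both lower. Loss or silencing of this region in the clofibrate culture could lower both. The 2 reductions were unequal, however. PTPRZ1 read under the background with clofibrate, while AASS read 1125 with DMSO and 605.6 with clofibrate, 1.86-fold lower. The other 3 expressed genes within 1 Mb had a median difference of 0.0586, but this is the value of the pseudogene RPS26P31, whose probes can share RNA with other copies. Another of the 3, at 0.12, has only a placeholder symbol. The remaining gene, FAM3C, differed by -0.19, and of genes below the filter but at least 2-fold over background with DMSO, ING3 differed by -0.17, CPED1 by -0.13, WNT16 by 0.36 and FEZF1 by -0.53. None of these was as low as AASS, but dim genes decide little, and a smaller change of the region, a change limited to PTPRZ1 and AASS and an unrelated coincidence stay open.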
